A study of Mus musculus with 12 samples.

How the data were processed

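RNA-seq libraries from mouse (C57BL/6) whole liver and from purified liver sinusoidal endothelial cells (LSEC) were compared between chow and a diet that induces nonalcoholic steatohepatitis (NASH), with 3 libraries in each of the 4 groups. Per the labels' protocols, LSEC were obtained by removing CD11b-positive cells from non-parenchymal liver cells and then collecting CD146-positive cells with magnetic beads. Liver libraries were made with a TruSeq kit that does not mark strand, per the labels. The labels state 36 weeks of NASH diet in a protocol that is attached to all samples, the chow samples included.

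Per the submitters' processing notes, FastQC, STAR, HTSeq, DESeq2 and Seurat were used with build mm10; their versions and settings are not given in the sources used here. The deposited tables, 1 per tissue, hold for each gene a normalized read signal per library, the authors' log2 fold change of NASH over chow, and the authors' p-value and adjusted p-value. The deposited signal values were read counts divided by 1 factor per library. Dividing each library's values by its smallest value above 0 gave whole reads, within a tolerance of 0.01, for 100% of values in every library. The recovered totals were 47000197 to 57397720 reads per liver library and 18527017 to 19402863 per LSEC library. Intervals from read counts cover counting error only. In the LSEC table a line above the column names gives the diet, but no column carries a replicate number from the labels. LSEC libraries are therefore numbered by position as names only.

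The tables held 16703 genes for liver and 16273 for LSEC. In each, 22 gene names had been turned into dates and 2 rows carried a repeated name. Of the gene symbols, 96.16% matched the GENCODE M21 annotation of mm10, which supplied the coordinates. Replicates of a group were compared with a chi-square statistic on recovered reads, which was 17.29 to 101.7 per degree of freedom, so no 2 libraries were copies. The labels do not say that replicates are separate animals, and the p-values measure the spread between these samples, which could be technical in part.

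Each tissue was tested alone with limma (version 3.58.1, R 4.3.3), with a trend in the variance, on log2(normalized reads + 1) and no filter. Adjusted p-values are Benjamini-Hochberg values, and genes under 0.05 were called. Fold changes are on this log2 scale, which understates the change of genes with few reads. Effects of the 2 tissues were compared per gene as the difference of the log2 fold changes over its standard error, with a two-sided normal p, over the 15766 genes in both tables. The 2 tables were normalized separately. Levels were set against each other only to choose liver-enriched genes, with mean normalized reads at least 32 times higher in the liver table, a ratio that depends on both scalings. The design named edgeR for counts and limma for normalized values, and the deposited unit called for limma. Tests with edgeR (4.0.16) and DESeq2 (1.42.0) on the recovered reads were alternatives.

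Before the data were examined, 31 gene lists were fixed, together with the tests, their first alternatives and the rule for genes to name. That rule takes, per tissue, the 6 largest rises and the 6 largest falls by log2 fold change among called genes with a mean of at least 50 normalized reads, without predicted genes. It adds Tsku and up to 3 members of each list with the smallest adjusted p. Some genes behind small counts are not reported here. For the difference between tissues it takes the 5 genes with the smallest p in each direction. Lists were tested with camera, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 62 tests of both tissues. Alternatives were another threshold, a fold threshold, filters, pseudocounts, centring, Holm adjustment, a replicate block, each library left out, and other settings of the list test. Other tools, scaling by total reads, a t distribution for the difference and the removal of liver-enriched genes were chosen after seeing the data.

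The steps were tested on simulated data. With 16703 simulated liver genes, limma recovered 60% of 2-fold and 97% of 4-fold changes, and 1.26% of its calls were false. With 16273 simulated LSEC genes it recovered 9% and 62%, with 2.74% false. The normal p for the difference between tissues recovered 70.1% of changes, but 39.3% of its calls were false, against 46.7% and 7.07% with a t distribution. Counts from the t distribution are therefore given beside those from the normal p. Few simulated genes were changed, 394 of 15788 for the difference, against 4505 called in the real data. Recovery and false share depend on this, so the rates do not carry over to the real counts.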

Results

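Whole livers and purified LSEC, the endothelial cells that line the liver's sinusoids, were profiled by RNA-seq in mice on chow and on a NASH diet. Each of the 4 groups had 3 libraries. The series title names the secreted liver protein Tsukushi, encoded by Tsku, as a regulator of the disease. The 2 comparisons ask which genes differ between NASH and chow in the whole organ and in its endothelial cells. Recovered depth was 47000197 to 57397720 reads per liver library and 18527017 to 19402863 per LSEC library.

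In NASH liver, most genes of the extracellular matrix and most markers of recruited macrophages were higher, resident Kupffer cell markers were divided, and most genes of cholesterol synthesis, fatty acid oxidation and amino acid metabolism were lower. Of 26 fibrillar matrix genes, 25 rose and none fell (25 adjusted over the list alone). Col1a1, a chain of type I collagen, went from 309 ± 70.3 to 11113 ± 1647 normalized reads (SD, n = 3), a log2 fold change of 5.18 ± 0.16 (SE; limma with Benjamini-Hochberg adjustment, adjusted p = 1.23e-07). Col1a1 lies on chromosome 11 at 94936224 to 94953042 in mm10. Col1a2 rose by 3.81 and Col6a3 by 3.38 on the log2 scale. Of 18 matrix remodelling genes 14 rose (14 adjusted over the list alone), among them the metalloproteinase Mmp12 at 5.57 and Adam8 at 4.71. Both lists passed camera, with adjusted p = 0.206 and 0.222 with an estimated correlation.

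Of 16 markers of recruited and lipid-associated macrophages, 15 rose in liver (16 adjusted over the list alone). The log2 fold change was 6.36 for Gpnmb, 4.44 for Itgax and 3.88 for Ccr2. All 15 MHC class II and dendritic cell genes rose (15 adjusted over the list alone), with H2-Eb1 at 2.96. Resident Kupffer cell markers were divided, with 7 higher and 3 lower (7 and 3 adjusted over the list alone). The scavenger receptor gene Cd163 fell by 5.75, Marco by 4.51 and Timd4, named after its value was seen, by 2.02, while the complement gene C1qb rose by 1.34. Whether the genes that rose were read from resident or from recruited macrophages was not tested. The Kupffer list had a median of 0.49 and a mean of -0.42, and camera did not pass it (adjusted p = 0.493). With fold change as the statistic it turned downward and passed (adjusted p = 0.0313). Of 27 chemokine and cytokine genes 23 rose, of 21 interferon-stimulated genes 19, and of 26 cell cycle genes 22 (23, 19 and 24 adjusted over each list alone). Of 18 T and NK cell markers 14 rose, and all 9 measured neutrophil markers did (17 and 9 adjusted over each list alone). Apart from the Kupffer list these lists passed camera, with adjusted p = 0.206 to 0.431 with an estimated correlation.

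Cholesterol synthesis genes fell in liver for 24 of 25 members (24 adjusted over the list alone), with a median log2 fold change of -1.81. Hsd17b7, on chromosome 1 at 169949535 to 169969241, went from 8778 ± 816 to 1167 ± 111 normalized reads (SD, n = 3). Msmo1 fell by 3.26 and Tm7sf2 by 2.48 on the log2 scale. Of 21 fatty acid oxidation genes 18 fell and 1 rose (18 and 1 adjusted over the list alone), with the omega-hydroxylase gene Cyp4a14 at -4.78. Of 20 genes of glucose, amino acid and urea metabolism 17 fell and 1 rose (17 and 1 adjusted over the list alone), with the urea cycle gene Asl at -2.93. The member of the fatty acid oxidation list that rose was Pdk4 (0.69) and that of the bile acid list Hsd3b7 (0.34), both named after their values were seen. Of 18 bile acid genes 12 fell and 1 rose, and of 18 hepatocyte identity genes 10 fell (12 and 1, and 11, adjusted over each list alone). With scaling by total reads their medians moved from -0.54 to -0.13 and from -0.52 to -0.10, with 6 lower and 3 higher and with 6 lower and 2 higher. With that scaling 14 fatty acid oxidation genes were lower and 3 higher, and 16 and 3 of the glucose, amino acid and urea list. Fatty acid synthesis genes were divided, with 8 higher and 7 lower (8 and 8 adjusted over the list alone), but with scaling by total reads 10 were higher and 5 lower and the median was 0.43. Srebf1, a regulator of lipid synthesis, rose by 2.05 and Acly fell by 0.98. The fatty acid synthesis list had a median of 0.01 and a mean of 0.17 against a downward camera statistic that did not pass (adjusted p = 0.819). The other lists of this paragraph passed camera, with adjusted p = 0.222 to 0.355 with an estimated correlation.

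**Figure D1:**
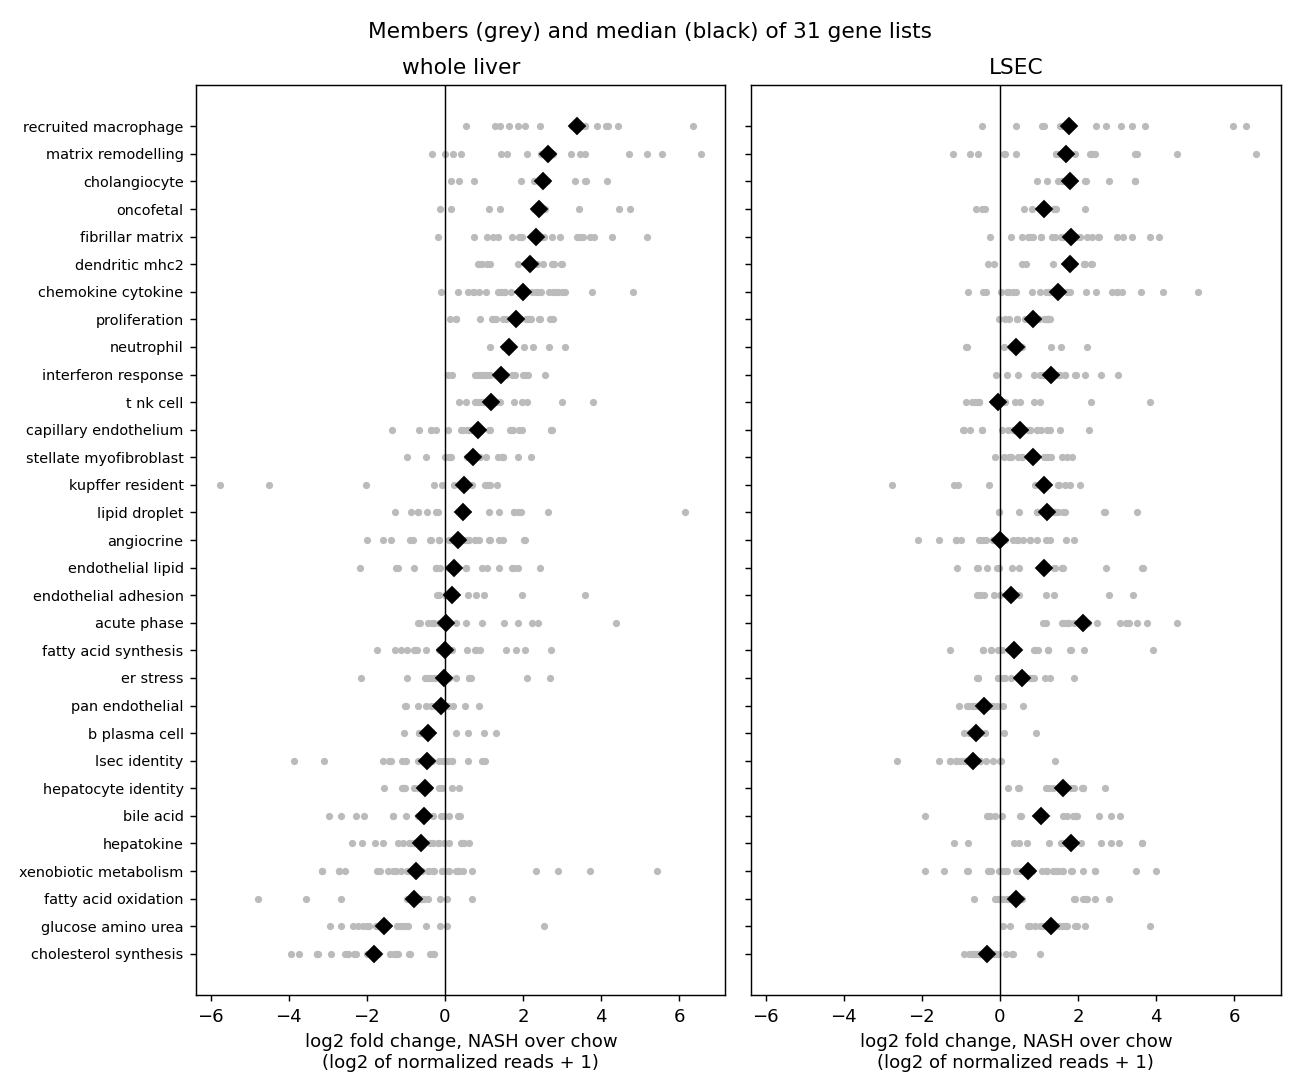
Log2 fold change of NASH over chow (x axis) for the members (grey points) and median (black diamonds) of the 31 gene lists (y axis) in whole liver (left) and LSEC (right). The cholesterol synthesis list has the lowest median in liver, -1.81, and a median of -0.34 in LSEC.

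The largest rises in liver by log2 fold change were Sdcbp2 (7.02), Sprr1a, Timp1 (6.57), Gpnmb (6.36), Gdf3 (6.15) and the lipid droplet gene Cidea (6.15). Sprr1a had 3 reads in all chow libraries together, and the ratio was 193 with a 95% counting interval of 65.9 to 940. The largest falls were Mup7 (-6.42), Mup12 (-6.14), Moxd1 (-5.97), Cd163 (-5.75), Mup1 (-5.75) and Cxcl13 (-4.94). Moxd1 had 858, 522 and 8.20 normalized reads in the chow libraries. The Mup genes are near-identical copies, so the share of reads each received is uncertain.

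In all, 7691 of 16703 liver genes passed the limma test, 4179 higher and 3512 lower in NASH. The authors' deposited table calls 7456, of which 7274 are among them. Scaling by total reads instead moved the median log2 fold change by 0.401 and called 7878 genes higher and 904 lower, so counts of lower genes are relative to the scaling. By camera 21 of the 31 lists passed, but 0 did with an estimated correlation, where 6 had an unadjusted p under 0.05 and the lowest adjusted p = 0.206. Other divisions of the 6 liver libraries passed 11 to 22 lists and at most 1 gene, so a list past the test sets the real groups little apart.

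**Figure D2:**
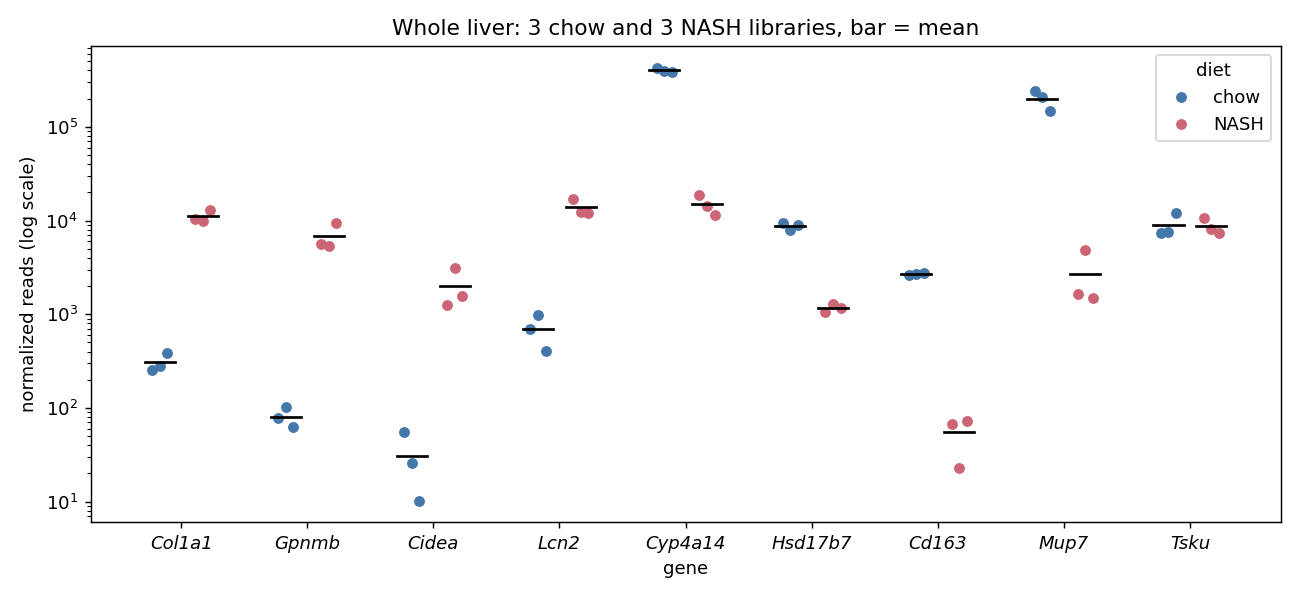
Normalized reads (y axis, log scale) of 9 genes (x axis) in the 3 chow and 3 NASH liver libraries (points), with group means (bars). Tsku overlaps between the diets, while the other 8 genes do not.

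In LSEC, NASH libraries had more reads from most matrix genes and from part of the recruited macrophage and lipid-handling genes, and fewer from 12 of 24 genes that mark sinusoidal endothelium. Of 24 sinusoidal endothelial markers 12 fell (17 adjusted over the list alone), and 1 rose, Lyve1 at 1.40, named after its value was seen (1 adjusted over the list alone). The lectin gene Cd209b, on chromosome 8 at 3917655 to 3926844, went from 663 ± 74.9 to 109 ± 35.6 normalized reads (SD, n = 3), a log2 fold change of -2.63 ± 0.25 (SE; limma with Benjamini-Hochberg adjustment, adjusted p = 0.00416). Ehd3 fell by 1.56 and Dnase1l3 by 1.28. Markers of endothelium in general moved with them, with a mean log2 shift of -0.409 ± 0.0256 (SE) beside -0.698 ± 0.0269 for the sinusoidal markers with a mean of at least 10 reads, and 2 of 18 fell and 1 rose (7 and 1 adjusted over the list alone). With scaling by total reads 8 sinusoidal markers were lower and 1 higher, and their median moved from -0.70 to -0.56. With that scaling 1 general marker was lower and 1 higher, and their median moved from -0.42 to -0.28. Of 26 fibrillar matrix genes 18 rose (23 adjusted over the list alone). Col1a1 rose by 4.08, Col3a1 by 3.37 and Fn1, which encodes fibronectin, by 2.54 on the log2 scale. Markers of stellate cells, which make such matrix, had a median of 0.84 with 2 of 17 higher, Pdgfrb (1.72) and Rgs5 (1.85) (2 adjusted over the list alone). Acta2, a marker of myofibroblasts, had 80.4, 3193 and 1003 normalized reads in the chow libraries and 843, 1483 and 657 in the NASH libraries. Of 19 endothelial lipid genes 8 rose and 1 fell (10 and 3 adjusted over the list alone), with the fatty acid receptor gene Cd36 at 1.40, Pparg at 1.60 and Cd300lg at -1.10. Among angiocrine genes, which encode endothelial signals to neighbouring cells, 4 of 26 fell and 1 rose (6 and 5 adjusted over the list alone), with Dkk3 at -2.10, Bmp6 at -1.56 and Bmp2 at -1.12. The others, named after their values were seen, were Wnt2 (-1.14) and Igf1 (1.69). Camera did not pass the angiocrine list (adjusted p = 0.369), whose statistic was downward against a median of 0.01 and a mean of 0.05. The other 5 lists passed camera, with adjusted p = 0.124 to 0.43 with an estimated correlation, and the stellate list lost its call without the first chow library (adjusted p = 0.0667).

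Part of the macrophage markers were also higher in the NASH LSEC libraries, although CD11b-positive cells had been removed. Of 16 recruited macrophage markers 9 rose (13 adjusted over the list alone), with Lgals3 at 2.47 and Cd63 at 1.68. Of 13 Kupffer cell markers 5 rose and 1 fell (9 and 3 adjusted over the list alone). Adgre1 was at 1.78, C1qb at 1.66 and Cd5l at 2.04, and C1qa and C1qc, which rose, and Cd163 (-2.77) were named after their values were seen. The Kupffer cell gene Clec4f, which did not pass, had 5667, 3528 and 1949 normalized reads in the chow libraries and 5730, 8636 and 6630 in the NASH libraries. Of 15 MHC class II and dendritic cell genes 8 rose, of 21 interferon-stimulated genes 12, and of 26 cell cycle genes 11 (10, 16 and 19 adjusted over each list alone). These lists passed camera, with adjusted p = 0.206 to 0.587 with an estimated correlation. The Kupffer list lost its call without the second NASH library (adjusted p = 0.132), with a correlation of 0.05 (0.0594) and with fold change as the statistic (0.177). Hepatocyte transcripts varied between libraries within a diet. Alb, the albumin gene, had 11003, 61571 and 5800 normalized reads in the chow libraries and 27790, 34837 and 54247 in the NASH libraries. By limma 0 of 18 hepatocyte identity genes passed, over all genes or adjusted over the list alone, with a median log2 fold change of 1.62. The list passed camera, with adjusted p = 0.405 with an estimated correlation. Of its genes, 6 had an unadjusted p under 0.05, 0 passed edgeR and 4 passed DESeq2.

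The largest rises in LSEC were Mmp12 (6.55), Gpnmb (6.31), Ctsj (5.99), Atp6v0d2 (5.97), Cfap69 (5.04) and Gdf3 (4.95). Gpnmb and Atp6v0d2 are in the recruited macrophage list, so carried-over macrophages may add to their rises. These ranks do not show which cells held the reads. The largest falls were Fam101a (-5.71), Klhdc8a (-4.04), Cxcl13 (-3.90) and the type IV collagen genes Col4a3 (-3.85) and Col4a4 (-3.58). Mup7 had 476 reads in the chow libraries and 0 in the NASH libraries. That was 177-fold lower against a floor of 3 reads over the group and at least 143-fold lower by the 95% counting interval. Most of these reads came from 1 chow library. Mup7 also fell in whole liver (-6.42), and hepatocyte transcripts varied between LSEC libraries, so a change within endothelial cells is not shown. Calls of some named genes ended when 1 library was left out, by limma's adjusted p. Those of Ctsj (0.0514 and 0.0609) and Atp6v0d2 (0.0512 and 0.0609) ended without the second or the third NASH library. Those of Ehd3 (0.051), Cd300lg (0.0521) and Dnase1l3 (0.0666) ended without the third NASH library, and that of Dnase1l3 also without the third chow library (0.054). Gdf3 (0.0561 to 0.0901) lost its call without the third chow library or any NASH library, Cxcl13 (0.0636 to 0.0691) without the third chow or the first or the third NASH library, and Mup7 (0.0858 to 0.136) without the first chow or any NASH library. Pdgfrb (0.0502 to 0.107) lost it without the first or the third chow or any NASH library, and Rgs5 (0.111 to 0.134) and Adgre1 (0.0572 to 0.0921) without the third chow or any NASH library. C1qb (0.092 to 0.12) and Cd5l (0.0662 to 0.0879) lost it without any 1 NASH library, and Bmp2 (0.051 to 0.0561) without the third chow or the second or the third NASH library. Rgs5 also missed the threshold with edgeR (0.0574), and Gdf3 (0.0643) and Mup7 (0.132) did in limma with pseudocounts of 0.1 and 10.

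In all, 1319 of 16273 LSEC genes passed the limma test, 853 higher and 466 lower in NASH. The authors' deposited table calls 2539, of which 1291 are among them. Scaling by total reads moved the median log2 fold change by 0.135 and called 1164 genes higher and 273 lower. The count was 255 without the third chow library, and 474, 241 and 124 without the first, the second and the third NASH library. By camera 22 lists passed and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05 and the lowest adjusted p = 0.124 belonged to the sinusoidal endothelial list. Other divisions of the 6 LSEC libraries passed 7 to 20 lists and at most 1 gene.

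**Figure D3:**
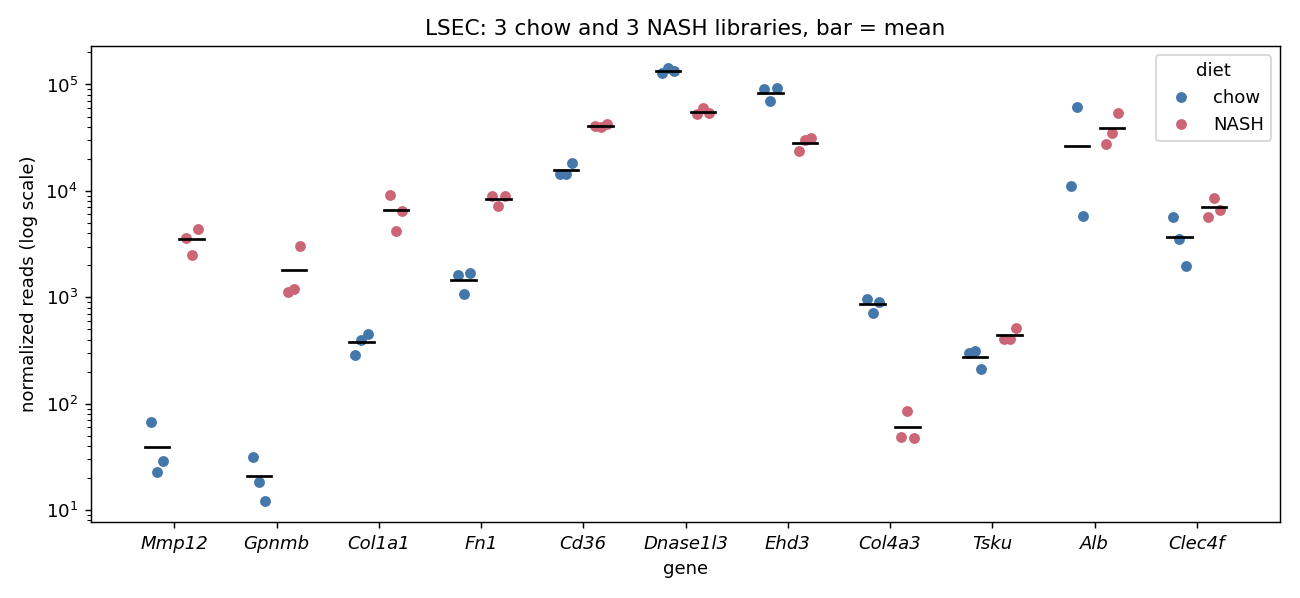
Normalized reads (y axis, log scale) of 11 genes (x axis) in the 3 chow and 3 NASH LSEC libraries (points), with group means (bars). Alb reached 61571 in a chow library and 5800 in another, while Dnase1l3 was lower in every NASH library.

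Tsku lies on the minus strand of chromosome 7 at 98350668 to 98361328 in mm10. In liver it had 8987 ± 2596 normalized reads on chow and 8749 ± 1753 in NASH (SD, n = 3). The log2 fold change was -0.02 (95% interval -0.45 to 0.41; limma with Benjamini-Hochberg adjustment, adjusted p = 0.942), and its sign turned with scaling by total reads (0.40). In LSEC Tsku had 276 ± 55.5 and 443 ± 62.7 normalized reads, a log2 fold change of 0.69 (0.21 to 1.17) that missed the threshold in limma (adjusted p = 0.0859). In the authors' deposited table the LSEC adjusted p of Tsku is 0.0288. Hepatocyte transcripts varied between LSEC libraries, so a change of Tsku within endothelial cells is not shown.

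The NASH effect differed between liver and LSEC for 4505 of 15766 genes by the normal p and for 3073 with a t distribution. Of the 4505, 2474 had the higher fold change in liver and 2031 in LSEC, against 1813 and 1260 with a t distribution and 2111 and 1000 with the interaction term of edgeR. Lgals1, which encodes galectin-1, had log2 fold changes of 3.36 in liver and -0.78 in LSEC, and Htra1 2.60 and -1.39. Fn1 was at -0.17 in liver and 2.54 in LSEC, and Steap2 at 0.30 and 3.98. Whole liver holds LSEC among other cells, so a difference does not show which cells changed. Among genes called in both tissues, 634 were higher in both, against 218.4 for independent lists, and 119 were lower in both, against 101.2. Higher in liver and lower in LSEC were 90, against 119.5, and the reverse held for 64, against 185. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.417.

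**Figure D4:**
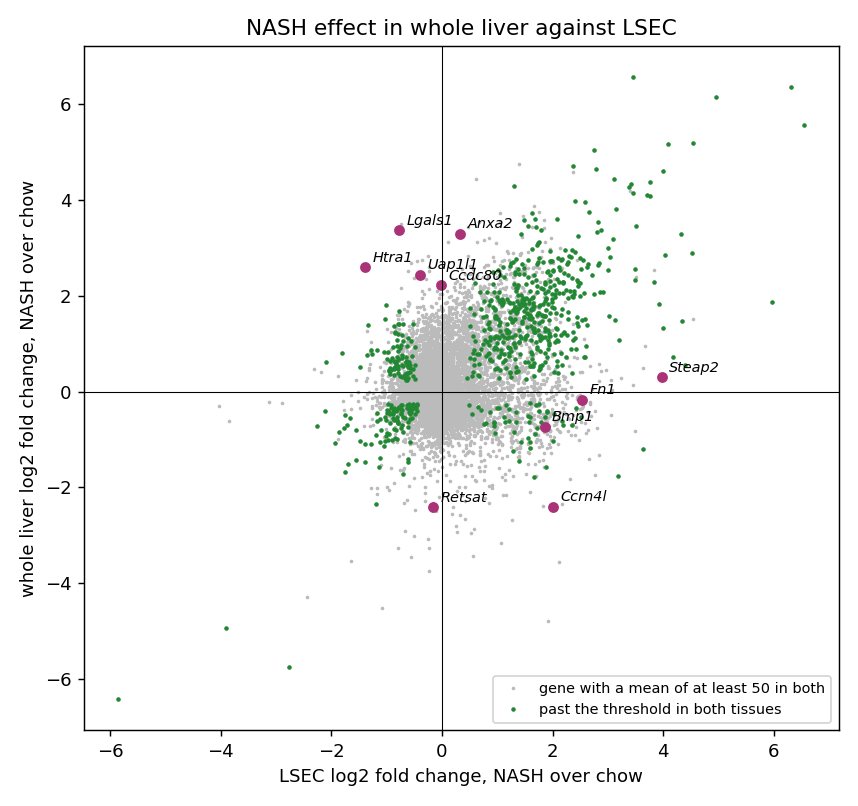
Log2 fold change of NASH over chow in LSEC (x axis) and whole liver (y axis) for 11274 genes with a mean of at least 50 normalized reads in both (grey), those called in both tissues (green) and 10 named genes (purple). Fn1 and Steap2 lie near 0 in liver and above 2 in LSEC.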

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

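The tests of a common amount per library, of macrophages carried over, of a lower endothelial share, of a smaller hepatocyte share, of the scaling and of regroupings with the liver groups kept were chosen after the results they measure had been seen. The NASH effect differed between whole liver and LSEC for 4505 genes. Of 100 drawn of the 200 regroupings within the tissues, 1, the real one, gave as many, and the highest other gave 4336. The 88 draws that changed the liver diet groups lost the liver effect itself and gave 0 to 1796, so this share does not speak to the LSEC part. Of all 20 splits of the LSEC libraries with the liver groups kept, 3 gave as many as the real 4505, and the highest other, 6575, was the one with the LSEC diets exchanged. These 20 are too few for a share under 0.05. All of them keep the liver effect, and the lowest other count was 2024, so they cannot decide whether the difference is chance. With a t distribution the real count was 3073 and the highest other 5438.

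The genes singled out by the smallest p of this difference were higher in the liver comparison for Lgals1 (4.14, liver minus LSEC log2 fold change), Uap1l1 (2.83), Htra1 (3.99), Ccdc80 (2.23) and Anxa2 (2.97). The difference was negative for Ccrn4l (-4.41), Bmp1 (-2.59), Steap2 (-3.68), Fn1 (-2.70) and Retsat (-2.26). In 7 lists most members differed in 1 direction by the normal p. The liver effect was above for 15 fibrillar matrix genes. The LSEC effect was above for 12 hepatocyte identity, 20 cholesterol synthesis, 12 fatty acid synthesis, 19 fatty acid oxidation, 16 glucose, amino acid and urea, and 12 hepatokine genes. With a t distribution these counts were 12, 3, 19, 7, 17, 8 and 5. The lists held 26, 18, 25, 19, 21, 20 and 21 genes in this order. Of the 7 lists only cholesterol synthesis and fatty acid oxidation then kept a majority of members.

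Liver-enriched genes, at least 32 times higher in the liver than in the LSEC table, which were normalized separately, had a median log2 fold change of 1.30 in LSEC and -0.54 in liver over 687 genes. Of them, 94.03% were higher in the second LSEC chow library than in the third, which is consistent with a common amount of hepatocyte RNA that varies between preparations. Whether that RNA sets the NASH effect stays open, since the LSEC effect followed the liver effect with a Spearman rho of only 0.2524 across these genes, between the bounds set in advance. A biological change of these genes within endothelial cells was not tested.

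Of recruited macrophage markers 9 of 16 rose in the NASH LSEC libraries, and of Kupffer cell markers 5 of 13 rose and 1 fell, although the sort removed CD11b-positive cells. Across 29 genes of the 2 macrophage lists, 3 of them also in another list, the LSEC effect followed the liver effect with a Spearman rho of 0.7906, as macrophages that pass the sort would give, so carried-over macrophages may account for it; the Kupffer cell gene Clec4f had 5667, 3528 and 1949 normalized reads on chow and 5730, 8636 and 6630 in NASH. A lower endothelial share with an unchanged mix of other cells would shift their markers alike. Recruited macrophage markers lay 2.20 ± 0.257 (SE) above T and NK markers in their log2 shift, 8.562 standard errors. Their gap to cholangiocyte markers was only 0.462 ± 0.867. The first gap argues against an unchanged mix only. In whole liver the 2 lists also rose unequally, with mean log2 fold changes of 3.01 and 1.41. A lower endothelial share with a changed mix therefore stays open for the recruited markers. For Kupffer markers a lower share cannot be told apart, since their gap to T and NK markers was 0.6244 standard errors with 3 libraries per group. A change within the macrophages and expression of these genes by endothelial cells stay open and were not tested.

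Cholesterol synthesis genes fell further in NASH liver than liver-enriched genes. A smaller hepatocyte share would lower both alike, but no draw of liver-enriched genes in 10000 had so low a median (a share of 1e-04, the smallest the draws can give), and the gap was -1.48 ± 0.25 (SE). The glucose, amino acid and urea list had a share of 1e-04 and a gap of -0.832 ± 0.188 (SE). Fatty acid oxidation had 0.037 and -0.538 ± 0.0381. The draws treat genes as independent, but the estimated correlations between genes were 0.456, 0.658 and 0.438 for the 3 lists in this order. The shares are therefore too low, and 0.037 cannot be relied on. The gaps rest on the spread between libraries and do not have this limit, but they are differences of means. The list medians were -1.81, -1.57 and -0.792, against -0.524, -0.522 and -0.523 for liver-enriched genes. For fatty acid oxidation the medians lay closer together than the means, on which large falls such as that of Cyp4a14 (-4.78) weigh. Its gap therefore does not show a fall of the whole list beyond liver-enriched genes. With scaling by total reads the list medians were -1.397, -1.154 and -0.3759. This scaling moved the median of all liver genes by 0.401, and the lists moved with it. The first 2 lists still fell well below 0 under this 1 other scaling, which says nothing of further scalings. For fatty acid oxidation the scaling stays open. A response of these pathways to the diet was not tested and stays open for all 3 lists.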

How the results depend on the processing

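Other tools, scaling by total reads, list tests with libraries left out, the t distribution and the removal of liver-enriched genes were tests chosen after seeing the data. The liver count of 7691 became 4960 at adjusted p under 0.01, 3239 with at least 2-fold and 663 with Holm adjustment, by construction of stricter thresholds, and 5863 to 7407 with 1 library left out. The LSEC count of 1319 became 126 at adjusted p under 0.01 and 17 with Holm adjustment, and 124 to 1171 with 1 library left out, where fewer samples were tested. With edgeR on recovered reads the counts were 7356 in liver and 1214 in LSEC, and DESeq2 gave 7432 in liver. The LSEC count was 2503 with DESeq2 on recovered reads and 2539 in the authors' deposited table, and the cause was not tested. In simulated LSEC data, with few genes changed, 27.4% of DESeq2 calls were false, against 2.74% for limma. DESeq2 recovered 57% of 2-fold and 94% of 4-fold changes there, against 9% and 62% for limma. These rates depend on the share of changed genes and do not carry over to the real counts. The main test had no filter, so the alternative without a filter was the main test.

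With an estimated correlation 0 liver and 0 LSEC lists passed camera, against 21 and 22, and 10 divisions cannot give a share under 0.05: for genes 1 of 10 and 1 of 10 reached the real counts of 7691 and 1319 (highest other 1 and 1), for lists 3 of 10 in liver (highest other 22) and 1 of 10 in LSEC (highest other 20). List counts were 21 to 22 in liver and 21 to 24 in LSEC with 1 library left out. Apart from the estimated correlation, calls ended with a correlation of 0.05 for the LSEC Kupffer (adjusted p = 0.0594) and fatty acid synthesis lists (0.0819), and with fold change as the statistic for the LSEC Kupffer (0.177), LSEC capillary (0.178) and liver stellate lists (0.0854). In LSEC they also ended without the second NASH library for Kupffer markers (0.132), without the third NASH library (0.0914) or liver-enriched genes (0.193) for fatty acid synthesis, without the first chow library for stellate markers (0.0667) and without the third chow library for glucose, amino acid and urea genes (0.157). Lists not past the threshold gained a call, in the same direction, in 3 tests in liver and 12 in LSEC. The difference count of 4505 became 2962 at adjusted p under 0.01 and 3565 to 4760 with 1 library left out.

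Liver Tsku, never called, turned sign with centring (0.0495) and total reads (0.40), and ranged from -0.18 to 0.21 with 1 library left out, above 0 without the third chow (0.21), the second NASH (0.03) or the third NASH library (0.09). By camera the Kupffer list in liver turned downward and passed with fold change as the statistic (adjusted p = 0.0313). With the background filter the B and plasma cell list in liver turned upward and did not pass (adjusted p = 0.946). With 1 library left out, lists not past the threshold turned in liver for B and plasma cells (0.437 to 0.986; turned at 0.726, 0.986 and 0.691) and fatty acid synthesis (0.532 to 0.916; turned at 0.916 and 0.824). In LSEC these were T and NK cells (0.0378 to 0.951; turned at 0.439 and 0.909), B and plasma cells (0.0447 to 0.694; turned at 0.527) and neutrophils (0.131 to 0.946; turned at 0.946). The cause was not tested. Of the named genes called, 98 of 99 in liver, 25 of 71 in LSEC and 10 of 10 for the difference kept their call with each library left out, and none changed sign. In LSEC 12, 10 and 31 calls ended without the first, the second and the third chow library and 26, 37 and 45 without the first, the second and the third NASH library. Holm adjustment ended 31 and 62 calls.

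The replicate block moved the liver count to 7447, left 21 lists and ended the call of 1 named gene, Cr2 (limma adjusted p = 0.0575). Same-numbered liver libraries correlated at -0.03, -0.03 and 0.18 and not every library correlated best with its own number. No paired analysis was possible for LSEC because its columns carry no numbers. LSEC libraries held fewer reads than liver libraries, and depth limits calls of genes with few reads.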

Other observations

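Scaling by total reads and the tests with edgeR and DESeq2 were chosen after the data were seen. Of 14 cholangiocyte markers 13 were called higher in NASH liver (13 adjusted over the list alone). The osteopontin gene Spp1, which is also in the recruited macrophage list, had a log2 fold change of 3.58 and Tspan8 3.33. The list passed camera, with adjusted p = 0.325 with an estimated correlation. Of 11 genes high in fetal liver or liver tumours 9 were called higher (9 adjusted over the list alone), with H19 at 4.75 and Ly6d at 4.45, and adjusted p = 0.206 with an estimated correlation. In liver 15 of 24 sinusoidal endothelial markers were called lower and 2 higher, Cd4 and Lyve1, named after their values were seen (15 and 2 adjusted over the list alone), with Ehd3 at -1.44 and adjusted p = 0.268 with an estimated correlation. With scaling by total reads the median of this list moved from -0.45 to -0.03, with 9 lower and 7 higher.

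Among the other lists past camera in liver, 10 of 17 stellate cell markers were called higher and 2 lower, 18 and 3 of 26 capillary endothelial genes, 7 and 18 of 37 xenobiotic metabolism genes, and 2 and 10 of 21 hepatokine genes. Adjusted over the list alone these were 10 and 2, 19 and 4, 7 and 20, and 2 and 10, and the lists had adjusted p = 0.206 to 0.43 with an estimated correlation. The stellate list lost its call with fold change as the statistic (adjusted p = 0.0854), and with scaling by total reads the medians of the xenobiotic and hepatokine lists moved from -0.74 to -0.32 and from -0.61 to -0.19, with 12 higher and 15 lower and with 4 and 8. With that scaling stellate markers gave 13 and 1. In lists not past camera (adjusted p = 0.13 to 0.867) lipid droplet genes gave 10 and 5, angiocrine genes 13 and 7, endothelial lipid genes 8 and 5, ER stress genes 5 and 6, pan-endothelial genes 2 and 5, acute phase genes 7 and 1, adhesion genes 4 and 0, and B and plasma cell genes 2 and 0. Adjusted over the list alone these were 10 and 5, 13 and 7, 9 and 6, 5 and 6, 2 and 5, 7 and 1, 3 and 0, and 1 and 0. The ER stress list had a median of -0.02 and a mean of 0.09, and its median and that of the pan-endothelial list turned with scaling by total reads, where ER stress genes gave 10 higher and 2 lower and pan-endothelial genes 8 and 2. With that scaling acute phase genes gave 11 and 1, adhesion genes 9 and 0, lipid droplet genes 10 and 3 and angiocrine genes 15 and 4. The acute phase list passed camera without the second chow (adjusted p = 0.0313) or the third NASH library (0.0239), and the lipid droplet list with fold change as the statistic (0.0237).

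Small counts in liver, with genes named after their values were seen, were Ecm1 and Vipr1 for lower stellate markers, Aqp1, Cxcl12 and Gja4 for lower capillary genes, and Itih3 for the lower acute phase gene. Higher adhesion genes were Icam1, Jam3, Sele and Vcam1, and higher B and plasma cell genes Cd22 and Cr2. The limma call of Cr2 ended with any 1 of the 6 liver libraries left out (adjusted p = 0.0524 to 0.172). It also ended with the replicate block (0.0575) and with DESeq2 (0.0998). Mcam and Sox18 were the higher and Flt1, Kdr, Ptprb, Robo4 and Tek the lower pan-endothelial genes. Lower lipid droplet genes were Cideb, Fabp1, G0s2, Plin5 and Pnpla2, and higher ER stress genes Atf3, Chac1, Ddit3, Sdf2l1 and Trib3.

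In LSEC 7 of 17 lipid droplet, 9 of 18 matrix remodelling, 8 of 27 chemokine and cytokine, 5 of 14 cholangiocyte, 6 of 26 capillary endothelial and 4 of 21 hepatokine genes were called higher (9, 12, 15, 12, 13 and 7 adjusted over each list alone). Of fatty acid synthesis genes 3 of 19 were called higher, Fasn, Mlxipl and Scd1, and of acute phase genes 2 of 17, Cp and Lcn2. Of the fatty acid oxidation list 1 of 21 members was called higher, Pdk4. For these 3 lists the counts were 6, 2 and 7 adjusted over each list alone. Of 25 cholesterol synthesis genes 1 was called lower, Dhcr7, and of 18 pan-endothelial genes Cldn5 and Eng lower and Mcam higher (0, 7 and 1 adjusted over each list alone). These lists passed camera, with adjusted p = 0.206 to 0.471 with an estimated correlation. In LSEC, hepatocyte and cholangiocyte markers with a mean of at least 10 reads had mean log2 shifts of 1.52 ± 0.855 and 2.01 ± 0.682 (SE). Which cells held the reads of these lists was not tested, so changes within endothelial cells are not shown. The fatty acid synthesis list lost its call without the third NASH library (adjusted p = 0.0914), with a correlation of 0.05 (0.0819) and without liver-enriched genes (0.193), and the capillary list with fold change as the statistic (0.178). The cholangiocyte genes were Ankrd1, Cd24a, Cftr, Cldn4 and Tspan8, the hepatokines Angptl4, Igf1, Inhba and Serpinb1a, and the lower genes of the chemokine and capillary lists Csf1 and Aqp1, of which Tspan8, Igf1, Csf1 and Aqp1 were named after their values were seen. Without the third NASH library the calls of the other genes named here ended by limma (adjusted p = 0.0648 to 0.167), except that of Angptl4. Calls also ended without the first or the second NASH library for Scd1 (0.0643 and 0.0821), without these or the third chow library for Fasn, Serpinb1a and Mcam (0.0652 to 0.109), and without the third chow or the second NASH library for Cftr and Cldn4 (0.0512 to 0.0691). They ended without the third chow or the first or the second NASH library, and without the first chow library for Mlxipl or the second chow library for Inhba and Cldn5 (0.0575 to 0.133). Cp and Cd24a lost theirs without any 1 chow or the second NASH library (0.0649 to 0.106), and Ankrd1, Pdk4, Eng and Dhcr7 without any 1 of the other libraries (0.0516 to 0.156). Dhcr7 also missed the threshold with edgeR (0.0568), and Dhcr7 (0.0997) and Eng (0.0744) with scaling by total reads.

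Lists not past camera in LSEC (adjusted p = 0.0618 to 0.616) had 2 of 18 T and NK cell markers higher, Gzmk and Pdcd1, with a median of -0.04 and a mean of 0.27, and 1 of 36 xenobiotic genes higher, Gstm3, and 1 lower, Sult1a1. They had 1 of 11 oncofetal genes higher, Cd24a, and 1 of 11 adhesion genes, Madcam1 (2, 1 and 0, 3 and 4 adjusted over each list alone). The median of the T and NK list turned with scaling by total reads. With fold change as the statistic the bile acid (adjusted p = 0.000555), xenobiotic (0.000202), oncofetal (0.0386) and B and plasma cell lists (0.0338) passed, and with ranks the xenobiotic list (0.0332). With 1 library left out, the bile acid (0.000161) and xenobiotic lists (6.73e-07) passed without the second chow library, the xenobiotic (0.00511) and oncofetal lists (0.0156) without the first NASH library, the B and plasma cell (0.0447) and ER stress lists (0.0375) without the third NASH library, and the T and NK list (0.0378) without the first chow library. By limma the call of Pdcd1 ended without the third NASH library (adjusted p = 0.0521), and that of Gstm3 without the first or the third chow or the second or the third NASH library (0.0525 to 0.102). Calls ended without any 1 NASH library or the third chow library, and also without the first chow library for Gzmk (0.0667 to 0.126) and Madcam1 (0.0737 to 0.131) or the second for Sult1a1 (0.068 to 0.165). Sult1a1 missed the threshold with edgeR (0.0531) and total reads (0.0737), and Madcam1 with DESeq2 (0.0642) and in the authors' deposited table (0.0615). By limma 0 genes passed among 18 bile acid, 20 glucose, amino acid and urea, 18 ER stress, 10 B and plasma cell and 8 neutrophil genes. At unadjusted p under 0.05 there were 4, 3, 3, 0 and 2, by edgeR 0, 0, 1, 0 and 0, and by DESeq2 1, 1, 2, 0 and 0. The glucose, amino acid and urea list passed camera, with adjusted p = 0.587 with an estimated correlation, and lost its call without the third chow library (adjusted p = 0.157).

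The Mup genes and other genes known to be higher in male mouse liver were among the largest falls, which led to the hypothesis that male-biased genes fall and female-biased genes rise in NASH liver. It was tested on 2 lists without genes seen among the largest changes; 8 male-biased and 11 female-biased members also stand in the fixed lists. Of 26 male-biased genes 18 were called lower and 2 higher (20 and 2 adjusted over the list alone), with a median log2 fold change of -1.14 (camera adjusted p = 4.24e-08, and adjusted p = 0.265 with an estimated correlation). Of 33 female-biased genes 8 were called higher and 13 lower (8 and 13 adjusted over the list alone), and the list did not rise (camera adjusted p = 0.2349). Its median was -0.45. Camera set both lists against all genes, and 687 liver-enriched genes had a median of -0.54 in liver. Whether male-biased genes fell further than liver-enriched genes was not tested. The hypothesis failed for the female-biased list, although Cyp2b9 and Cyp2a4, chosen after their values were seen, were at 3.72 and 4.33.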
